A study of Cicer arietinum with 8 samples.

How the data were processed

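Messenger RNA was sequenced from roots and shoots of 10-day-old chickpea seedlings (Cicer arietinum, genotype ICC4958) after 5 h in 1 of 4 conditions. Control seedlings stood in water, desiccated seedlings lay on tissue paper, salt-stressed seedlings stood in 150 mM NaCl, and cold-stressed seedlings stood in water at 4 ± 1 °C. The 8 libraries give 1 library per tissue and treatment, so no condition has a replicate. Groups were taken from the sample titles.

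The deposited values are FPKM (fragments scaled by exon length in kilobases and by the library's mapped fragments), 1 file per library. Per the labels and the series' design text, the authors filtered reads with NGS QC Toolkit, mapped them to the annotated chickpea genome with TopHat, computed FPKM with Cufflinks and tested differences with Cuffdiff. The versions of these tools, the genome build and the annotation release are not given in the sources used here. FPKM divides by gene length and by the library's total, so a few very abundant transcripts lower all other values of their library, and short loci can reach a high FPKM from few fragments. The deposited FPKM files hold 34193 loci each, of which 27248 carry annotated gene IDs and 6945 carry only a locus number. Several annotated IDs stand together on 448 loci, and 140 IDs appear on more than 1 locus, so reads could be split or merged there. A value of 0 in all libraries was found at 7835 loci. An exact 0 from an FPKM estimator can be a failed estimate, so such a value is described as listed at 0 and no single fold is printed against it. Counts of changed loci, correlations, means and fits take it as 0, so they include changes against such values.

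Total read numbers are not part of the values used here. Relative depth was estimated from the steps that single fragments make among values under 0.3 FPKM, since the size of such a step differs between libraries by the same ratio at every locus. Against the root control (1), the depth was 1.21 in root desiccation, 1.30 in root salinity, 1.27 in root cold, 1.30 in shoot control, 1.25 in shoot desiccation, 1.29 in shoot salinity and 1.30 in shoot cold. After this scaling, 57.7% of the 577 low loci examined were whole multiples of 1 step in every library within 5%, against 0.52% for random ratios. At those loci 1 FPKM stood for a median of 13.4 fragments at the root control's depth, so values near 1 FPKM carry a large counting error. Whole reads were not recovered for most loci, and no count test was run.

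Stress and control libraries of a tissue were compared by size alone. A locus counted as changed when log2(FPKM + 1) differed by at least 1 (2-fold) and FPKM was at least 1 in at least 1 of the libraries compared. Fold changes are on this scale, which understates changes of weakly expressed loci. With 1 library on each side, the difference has no replicate check and no p-value was computed. The overlap of responses between root and shoot was set beside the overlap of independent lists (the product of the list sizes over the loci considered). Within a tissue the stresses share their control library. Their overlap was therefore also set beside 100 simulations of unchanged libraries, with noise drawn from the closest pair of libraries of that tissue in 20 expression bins. That pair was desiccation and cold in root, and control and cold in shoot. These pairs differ in treatment, so the noise includes any real differences between them. Root desiccation and cold supply their own noise as the closest pair, so their excess over the simulation was fixed in advance.

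An additive model with tissue and treatment was fitted with limma 3.58.1 (R 4.3.3, empirical Bayes with a trend) to the 21907 loci with a mean of at least 1 FPKM over the 8 libraries. It has 3 residual degrees of freedom, which come from departures of the tissues' responses from each other. Its stress terms test what root and shoot share, and its tissue term tests root against shoot over the 4 treatments. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Nothing in the labels says that tissues came from separate sets of plants, so these p-values measure only the spread between the libraries at hand. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

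The steps were tested on simulated data. All 200 loci planted as changed in a simulated root desiccation library were counted, among 34193. The planted changes lay well past 2-fold, at well expressed loci and with little noise. That step therefore checks the counting itself and not the error of counts near 1 FPKM. In a simulation of the additive desiccation test on 21907 loci at the fitted spread, 0% of 50 planted 2-fold changes were recovered, 38% of 50 planted 4-fold changes, 98% of 50 planted 16-fold changes and 100% of 50 planted 64-fold changes. For root against shoot the shares were 2% at 2-fold, 82% at 4-fold, and 100% at 16-fold and 64-fold. Changes were planted only at loci expressed well above the filter, so these shares do not cover weakly expressed loci. The same simulations called 7 loci without a planted change for desiccation and 14 for root against shoot.

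The files do not pair the gene IDs with names or descriptions. None (0) of the 27571 distinct annotated IDs matched the reference gene table used here (29938 genes, assembly Cicar.CDCFrontier_v2.0), so loci are given by ID without names or positions. The 30 gene lists fixed as patterns on gene descriptions could not be applied. Loci to be printed were fixed before the data were examined. For each stress these were loci with at least 5 FPKM in any of the 4 libraries compared, changed the same way in both tissues and ranked by the smaller change. For the tissues they were the loci with the largest mean difference past the threshold and in the same direction in 4 of 4 treatments. At most 2 risers and 2 fallers of a ranking are printed where IDs have no names. Of the 48 top loci of the stress rankings, 36 had no annotated gene and 33 were listed at 0 in at least 1 of the libraries compared. The loci printed are therefore the first of each ranking with an annotated gene, a restriction chosen after the values were seen. The rankings for single tissues are not printed.

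The alternatives tried were pseudocounts of 0.1 and 5, a minimum of 5 FPKM, no filter, rescaling by median ratios, quantile normalization, a 4-fold threshold, fits without the trend or the treatment term, and fits that leave out treatments. Restriction to annotated gene models was added after the values were seen.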

Results

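The series asked which genes change in expression in chickpea roots and shoots under desiccation, salinity and cold. ICC4958 is a chickpea genotype, and all tissue came from 10-day-old seedlings treated for 5 h. There were 4 root and 4 shoot libraries, 1 for each of control, desiccation, salinity and cold. Between 19991 (root control) and 20488 (shoot control) of the 34193 loci reached 1 FPKM in a library. The sum of FPKM ran from 1194209 to 1467263 in root and from 2457120 to 3343299 in shoot. Loci without an annotated gene made up 48.0% to 54.1% of that sum in root and 73.2% to 78.7% in shoot. Sequencing depth was similar in 7 of the libraries, at 1.21 to 1.30 times that of the root control.

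The first comparison set each stress against the control of the same tissue. In root, salinity was associated with the widest change, with 3520 loci at least 2-fold higher and 2924 at least 2-fold lower than in the control. Root desiccation had 2493 higher and 1851 lower loci, and root cold had 2361 higher and 1940 lower. In shoot the order was different. Shoot desiccation had the most changed loci, 2188 higher and 2179 lower, followed by salinity with 1499 higher and 1463 lower and by cold with 603 higher and 442 lower. Under quantile normalization the balance turned in root salinity, with 3250 higher and 3298 lower, and in shoot desiccation, with 2112 higher and 2145 lower. With a pseudocount of 0.1 it turned in shoot desiccation (2787 higher, 3000 lower) and in shoot salinity (2010 higher, 2233 lower). Among loci at least 4-fold apart the higher ones prevailed, with 72.5% in shoot salinity and 62.6% in shoot desiccation. Changed loci made up 30.0% of those considered in root salinity (6444 of 21480) and 4.96% in shoot cold (1045 of 21055).

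Among annotated gene models the same order of stresses held in each tissue. Root salinity had 2401 higher and 1901 lower gene models, root desiccation 1548 and 1086, and root cold 1363 and 1263. Shoot desiccation had 1479 higher and 1610 lower gene models, shoot salinity 1049 and 725, and shoot cold 357 and 71. In shoot cold 83.4% of the changed gene models were higher, against 57.7% of all changed loci. The median log2 change over all loci considered ran from -0.05 (shoot salinity) to 0.05 (root desiccation) in the 6 comparisons. These are differences between pairs of libraries without replicates, so their number cannot be set against biological spread.

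**Figure D1:**
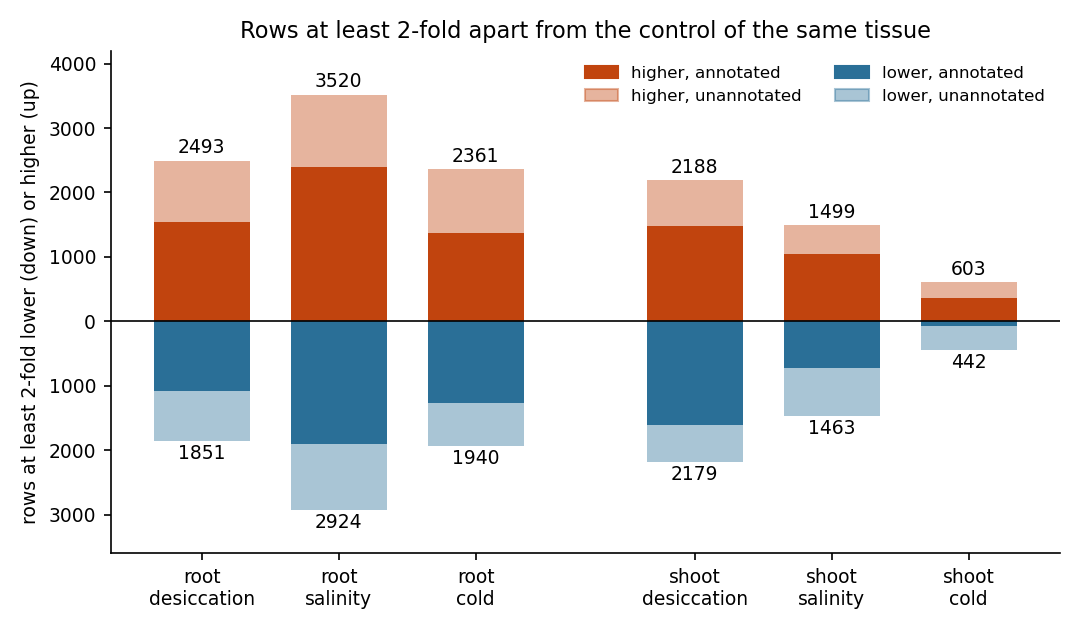
Number of loci at least 2-fold higher (up) or lower (down) than the control of the same tissue, for each tissue and stress (horizontal axis), with gene models in dark and loci without an annotated gene in light shades. Root salinity had the tallest bars (3520 higher, 2924 lower) and shoot cold the shortest (603 higher, 442 lower).

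Desiccation was followed by large increases of some gene models in both tissues. Ca_13297 stood at 2.55 FPKM in the root control and 244 FPKM in desiccated root, and at 1.48 FPKM in the shoot control and 451 FPKM in desiccated shoot. Its log2 change was 6.11 in root and 7.51 in shoot. Ca_06911 was higher by 5.01 (log2) in root, from 0.535 to 48.6 FPKM, and by 4.65 in shoot, from 59.95 to 1527 FPKM. In the other direction, Ca_10503 went from 40.9 to 4.46 FPKM in root and from 10.4 to 0.267 FPKM in shoot, log2 changes of -2.94 and -3.17. Ca_04974 went from 21.6 to 0.99 FPKM in root and from 46.5 to 6.79 FPKM in shoot, log2 changes of -3.51 and -2.61. Other stresses also moved these gene models, though not in every library. Ca_06911 stood at 16.2 FPKM under salinity and 3.08 FPKM under cold in root, and at 509 and 143 FPKM in shoot. Ca_10503 stood at 19.4 and 2.79 FPKM in root under these stresses, and at 12.3 and 4.87 FPKM in shoot. Ca_04974 stood at 1.08 and 0.937 FPKM in root, and at 19.04 and 47.4 FPKM in shoot.

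Under salinity Ca_13297 was again the gene model with the largest increase shared by the tissues, at 126 FPKM in root (log2 change 5.16) and 275 FPKM in shoot (log2 change 6.79). Ca_21463 was listed at 0 in the root control and stood at 28.7 FPKM in salt-stressed root. In shoot it went from 3.27 to 167 FPKM, a log2 change of 5.30. In shoot it also stood at 141 FPKM under desiccation and 18.7 FPKM under cold. In root it was at 0.292 FPKM under desiccation and listed at 0 under cold. Ca_18772 was lower in both tissues, from 6.90 to 0.706 FPKM in root and from 6.90 to 0.655 FPKM in shoot, log2 changes of -2.21 and -2.26. Ca_14119 went from 232 to 52.0 FPKM in root and from 12.7 to 1.15 FPKM in shoot, log2 changes of -2.14 and -2.66. The fall of Ca_18772 in root was seen under salinity alone. Its fall in shoot, and the falls of Ca_14119, were not particular to salinity. Under desiccation and cold Ca_18772 stood at 0.667 and 0.644 FPKM in shoot, though at 8.39 and 19.9 FPKM in root. Ca_14119 stood at 57.1 and 67.7 FPKM in root under these stresses, and at 0.185 and 12.5 FPKM in shoot.

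Cold had other leading gene models. Ca_01986 went from 0.475 to 122 FPKM in root and from 2.49 to 29.2 FPKM in shoot, log2 changes of 6.38 and 3.11. The same gene model also stood high in root under salinity (239 FPKM) and desiccation (80.6 FPKM), while in shoot it was at 1.28 and 0.348 FPKM under these stresses. Ca_08628 was listed at 0 in the root control and stood at 19.4 FPKM in cold root, and it went from 0.679 to 10.2 FPKM in shoot, a log2 change of 2.74. Ca_17506 went from 51.9 to 9.91 FPKM in root and from 24.5 to 4.43 FPKM in shoot, log2 changes of -2.28 and -2.23. Ca_17507 went from 196 to 43.3 FPKM in root and from 16.1 to 4.17 FPKM in shoot, log2 changes of -2.15 and -1.73. Both of these gene models were higher than the control in salt-stressed root, at 300 and 338 FPKM. Their falls were otherwise largely shared with other stresses. Under desiccation they stood at 13.3 and 36.2 FPKM in root. In shoot Ca_17506 stood at 1.09 FPKM under desiccation and 2.97 FPKM under salinity. Ca_17507 stood at 5.89 FPKM in shoot under salinity, but at 23.4 FPKM under desiccation.

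**Figure D2:**
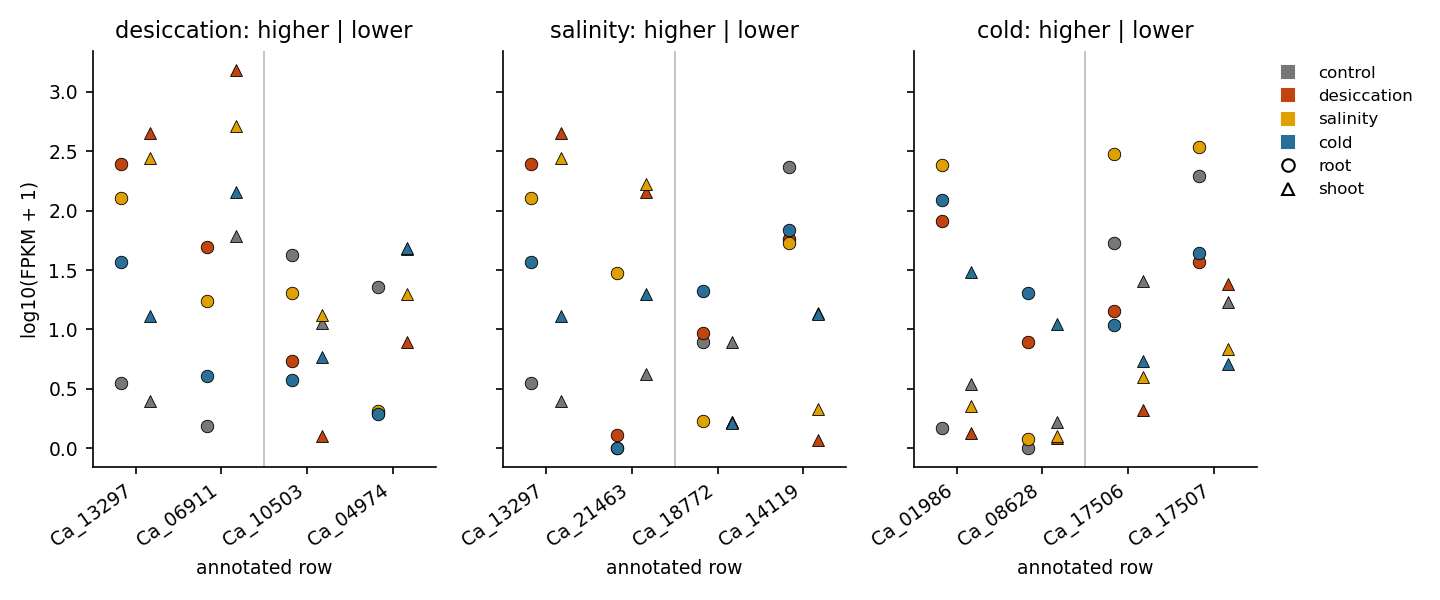
Expression of the gene models with the largest changes shared by root (circles) and shoot (triangles) under desiccation, salinity and cold (panels), as log10(FPKM + 1) on the vertical axis with 1 point per library, coloured by treatment. Ca_13297 lay lowest in the control of each tissue (2.55 FPKM in root, 1.48 FPKM in shoot) and highest under desiccation (244 and 451 FPKM).

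The next comparison asked how far the stresses moved the same loci within a tissue. In root, desiccation and cold moved largely the same loci, with 2884 changed the same way under both and 23 in opposite directions. Salinity shared 2005 loci with desiccation and 1924 with cold in root, with 215 and 271 in opposite directions. In shoot, desiccation and salinity went together, with 1805 loci changed the same way and 35 in opposite directions, while cold shared 369 loci with desiccation and 461 with salinity, with 97 and 29 in opposite directions. All 3 stresses moved 1497 loci the same way in root and 289 in shoot, against 51.4 and 6.01 for independent lists and 393 and 86.0 for simulated unchanged libraries that share a control. Salinity alone passed the 2-fold mark at 3670 root loci, against 858 for desiccation alone and 840 for cold alone. In shoot the numbers were 2373 for desiccation alone, 944 for salinity alone and 401 for cold alone.

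Comparisons with 1 shared control overlap by chance. Independent lists would share 398 loci in the same direction for root desiccation and cold, 565 for root desiccation and salinity, 568 for root salinity and cold, 282 for shoot desiccation and salinity, 93.8 for shoot desiccation and cold, and 63.4 for shoot salinity and cold. Simulated unchanged libraries against the shared control gave 871 loci in root and 234 in shoot. Among gene models alone they gave 38.5 and 17, where 1924 were shared by root desiccation and cold and 1271 by shoot desiccation and salinity. The covariance of the log2 changes was 0.909 for root desiccation and cold, 0.691 for root desiccation and salinity and 0.670 for root salinity and cold, against 0.237 simulated. In shoot it was 0.527 for desiccation and salinity, 0.201 for salinity and cold and 0.161 for desiccation and cold, against 0.137 simulated. The control library of a tissue cannot be split, so part of the excess may come from the shared control. For root desiccation and cold the noise came from that same pair, chosen as the closest. The excess of this pair over the simulation was therefore fixed in advance, and no conclusion is drawn from it. For the other root pairs, noise from the closest pair also favours an excess. The root control lay farther from each stressed root library than that pair lay apart, so their excess can come from the control. The same limit holds for the root loci moved the same way by all stresses. In shoot the noise came from control and cold, so the simulated values hold the shoot cold change itself.

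A direct comparison of the stressed libraries does not use the control. Desiccated and cold root differed at least 2-fold at 1620 loci, 500 of them gene models, whereas salt-stressed root differed from desiccated root at 6556 and from cold root at 6324. The first of these counts was 1034 with a minimum of 5 FPKM, 2495 and 609 with pseudocounts of 0.1 and 5, and 344 with a 4-fold threshold. Among the 16477 gene models with a mean of at least 1 FPKM, 2.88% were 2-fold apart between root desiccation and root cold, 15.3% between root control and root desiccation, and 15.5% between root control and root cold. Shoot control and shoot cold were 2.51% apart, and shoot desiccation and shoot salinity 6.65%. Salt-stressed root was 25.2% apart from the root control, 25.5% from desiccated root and 24.3% from cold root. Libraries of different tissues were 36.1% to 45.9% apart.

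**Figure D3:**
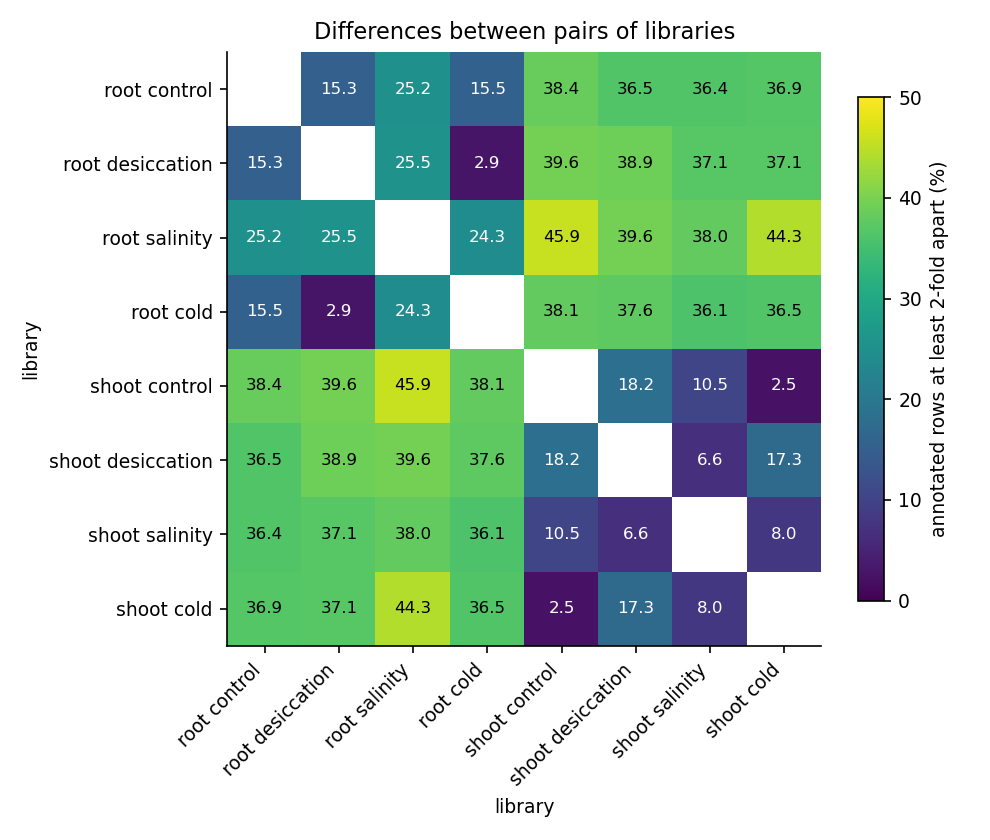
Percent of the 16477 gene models at least 2-fold apart on log2(FPKM + 1) for each pair of libraries (both axes list the 8 libraries, and the colour scale is in percent). Root desiccation and root cold (2.88%) and shoot control and shoot cold (2.51%) were the closest pairs, and root salinity lay 24.3% to 25.5% from the other root libraries.

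Root and shoot responses to a stress share no library, so their overlap is not made by a common control library. The labels do not say whether the tissues came from separate plants, so an effect on the control plants could be shared. Salinity moved 948 loci the same way in both tissues and 228 in opposite directions, where independent lists would give 338 and 334. Cold moved 381 loci the same way and 111 in opposite directions, against 74.5 and 73.1. Desiccation moved 555 loci the same way and 521 in opposite directions, against 314 and 315. Across loci, which are not independent replicates, Pearson's r of the root and shoot changes was 0.322 for salinity, 0.195 for cold and 0.0492 for desiccation, with Spearman's rho of 0.318, 0.0717 and 0.00373. These were 3 of 9 pairings of a root response with a shoot response. Root desiccation correlated more with shoot cold (r = 0.241, rho = 0.187) than with shoot desiccation, and more than root cold did with shoot cold. Root desiccation shared 390 loci in the same direction with shoot cold, against 71.5 for independent lists, and 89 in opposite directions, against 70.1. The overlap with shoot cold is therefore not particular to root cold. Root salinity correlated with shoot salinity (0.322) more than with shoot desiccation (0.21) or shoot cold (0.164).

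**Figure D4:**
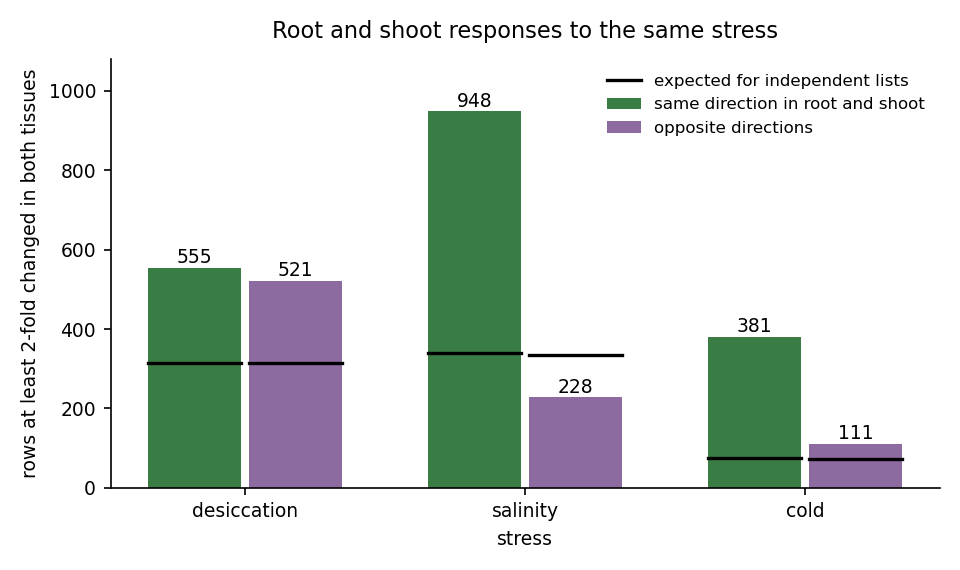
Loci at least 2-fold changed in both root and shoot under each stress (horizontal axis), as counts in the same direction (green) and in opposite directions (purple), with black lines at the counts for independent lists. Salinity gave 948 loci in the same direction against 228 in opposite directions, and desiccation 555 against 521.

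The additive model asked which loci responded to a stress by a like amount in root and shoot. For desiccation, 1 of 21907 loci passed the threshold: Ca_06911, with a mean log2 change of 4.83 (SE 0.29, limma adjusted p = 0.0359), higher in both tissues. Ca_13297 had larger mean changes, 6.81 under desiccation (SE 0.66, limma adjusted p = 0.145) and 5.98 under salinity (SE 0.66, limma adjusted p = 0.198), and did not pass. No locus (0) passed for salinity or cold with limma, where 2292 (10.5%) and 696 (3.18%) loci had an unadjusted p under 0.05, as did 1246 (5.69%) for desiccation. Chance alone gives 5%. The call of Ca_06911 was lost with a pseudocount of 0.1, without the filter, with quantile normalization, without the trend, with the salinity libraries (adjusted p = 0.122) or the cold libraries (0.246) left out, and with control and desiccation alone (0.621), while its log2 change stayed between 4.38 and 5.47 and limma's adjusted p ran from 0.0119 to 0.621. Differences between the responses of root and shoot count as error in this model. In simulation it recovered 38% of 4-fold desiccation changes planted at loci expressed well above the filter.

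The largest expression differences lay between the tissues. With limma 7899 of 21907 loci differed between root and shoot, 3797 higher in root and 4102 higher in shoot, and 6965 of them differed at least 2-fold on average. The direction was the same in 4 of 4 treatments for 3702 of the loci higher in root and 4064 of those higher in shoot. Ca_18235 had 19919 ± 13609.8 FPKM in root and 0.99 ± 0.783 FPKM in shoot (SD, n = 4 libraries under different treatments), a log2 difference of 13.14 (SE 0.54, limma adjusted p = 2.01e-05). In root it was highest in the control (39384 FPKM) and lowest under salinity (8675 FPKM). Ca_10598 stood at 1075 to 1302 FPKM in root, and in shoot it was listed at 0 under desiccation and reached 0.41 FPKM at most. Higher in shoot were Ca_06719, at 2610 to 3377 FPKM, and Ca_21523, at 2115 to 4301 FPKM. In root Ca_06719 was at 0.104 FPKM in the control and listed at 0 in the 3 stressed libraries, and Ca_21523 was at 0.813 FPKM under desiccation, at 0.302 FPKM under cold and listed at 0 in the other two. All 4 of these gene models passed the limma threshold and kept their direction in 4 of 4 treatments.

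Tissue-restricted gene models were a small part of those expressed. Of 10465 gene models with at least 5 FPKM in all 4 root libraries, 172 were under 1 FPKM in all 4 shoot libraries. Of 11031 with at least 5 FPKM in all 4 shoot libraries, 222 were under 1 FPKM in all 4 root libraries. The 4 libraries of a tissue differ in treatment, so their spread is not that of replicates.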

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

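Root and shoot moved in opposite directions at part of the loci that changed at least 2-fold in both tissues, and this difference between the tissues was not tested, because each rests on 1 library per tissue and treatment. Under desiccation 521 loci moved in opposite directions, against 315 for independent lists, and 297 of them were higher in root and lower in shoot. Under salinity 228 loci did so, against 334 for independent lists. Under cold 111 loci did so, against 73.1 for independent lists, and 32 of them were gene models, where 27.4 are given by independent lists.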

How the results depend on the processing

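Restriction to annotated gene models was chosen after the values were seen, and the other settings before the data were examined. Rescaling by median ratios and a minimum of 5 FPKM left the counts of loci changed against the control, and of shared loci where run, within 1.5 times, and quantile normalization did so for the changed loci. Dropping the filter cannot change a count of changed loci, since a 2-fold change on this scale needs at least 1 FPKM. A 4-fold threshold left 1254 loci for root desiccation, 1800 for root salinity, 1212 for root cold, 812 for shoot desiccation, 448 for shoot salinity and 146 for shoot cold. A pseudocount of 5 gave 2235, 3599, 2256, 2263, 1335 and 449 in that order. A pseudocount of 0.1 gave 1714 changed loci for shoot cold, and in shoot 661 shared by desiccation and cold and 786 shared by salinity and cold. With annotated gene models alone, fewer loci were considered, and 2634 changed in root desiccation, 2626 in root cold, 1774 in shoot salinity and 428 in shoot cold. Those changed the same way in both tissues numbered 366 for desiccation, 592 for salinity and 225 for cold. Gene models shared in direction numbered 1228 for desiccation and salinity and 1167 for salinity and cold in root, and in shoot 164 for desiccation and cold and 176 for salinity and cold. Gene models in simulated unchanged libraries shared 38.5 in root and 17 in shoot. Of 48 alternatives for the direct comparisons of stresses, 21 moved the count by more than 1.5 times. Counts in the text are therefore sizes under 1 setting, while the order of stresses within shoot, and salinity as the widest response in root, held under each of these settings.

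The additive desiccation test called 0 loci with a pseudocount of 0.1, without the filter, with quantile normalization, without the trend, with the control and desiccation libraries alone, and with the salinity or the cold libraries left out (leave-one-out range 0 to 0). With annotated gene models alone it called 2, Ca_06911 and Ca_09780 (log2 change 4.00, SE 0.32, limma adjusted p = 0.0484), the latter named after its value was seen. The adjusted p of Ca_06911 ran from 0.0119 to 0.621 over the alternatives, and the cause was not tested. Salinity and cold gave 0 calls under each alternative with limma. Root against shoot gave 6093 to 8260 calls over the other alternatives, and 5546 (cold libraries left out) to 6811 (desiccation libraries left out) when 1 treatment was left out. The gene models printed kept their direction under each alternative run for them, and their log2 values moved by more than 0.1 in 34 of 84 cases. With a pseudocount of 0.1 Ca_18235 went to 14.23, Ca_06911 in root desiccation to 6.26 and Ca_10503 in shoot desiccation to -4.84. The test of root against shoot is matched by treatment, and without the treatment term it gave 8088 calls. The alternatives for the fixed gene lists were not run. Depth limits values near 1 FPKM (a median of 13.4 fragments).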

Other observations

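All tests below were written down after the result they bear on was seen. Gene models typical of a tissue were followed as lists, chosen by a mean difference of at least 8-fold between root and shoot over the control and the stress libraries of the comparison. Root-rich gene models had a median log2 change in root of 0.41 under desiccation (673 gene models, 216 at least 2-fold higher and 92 lower), 0.32 under salinity (603, 241 higher and 156 lower) and 0.14 under cold (643, 160 higher and 110 lower). Their changes were wide, with quartiles of -0.33 and 1.32 under desiccation, -1.03 and 1.94 under salinity, and -0.61 and 0.99 under cold. The middle 95% of the medians of 10000 random lists of like mean expression over the 8 libraries ended at 0.09, 0.11 and 0.07 for these stresses. The lists were not matched on expression within a tissue. Tissue-rich gene models therefore lie above their random lists in their own tissue and below them in the other, where changes are understated. In shoot the medians of the same lists were 0.00 under desiccation, 0.14 under salinity and 0.03 under cold, where the random lists ended at 0.00, 0.02 and 0.00. Shoot-rich gene models had medians in root of -0.16 under desiccation, -0.12 under salinity and -0.19 under cold, where the random lists began at 0.01, -0.08 and -0.03. In shoot their medians were -0.22 under desiccation and -0.18 under salinity, where the random lists began at -0.09 and -0.05, and 0.07 under cold, where they ended at 0.01. These values describe single libraries. The falls of shoot-rich gene models in root share 1 root control, where 72 abundant ones stood at a median of 0.757% of their shoot control level. That level was 0.384% in root desiccation, 0.521% in root salinity and 0.453% in root cold. A difference in shoot RNA between these libraries cannot be told apart from a fall under stress.

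The difference between root and shoot stood apart from other groupings of the libraries. Without a treatment term, 1 of 35 splits into 4 and 4 gave as many loci as the real 8088, the real split itself. The highest other split gave 0. Each other split mixes the tissues, and 1 is the smallest number these splits can give, so they cannot exclude chance by themselves.

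Root desiccation and root cold lay closer to each other than either lay to the root control. Lower depth of the control is argued against by the 6679 gene models with a mean of at least 20 FPKM, where the smaller share 2-fold apart from the control (16.9%) was 6.81 times that between desiccation and cold (2.49%). Shoot RNA would have to make up 50% of the root control to put 1014 gene models 2-fold lower there. Yet 72 abundant shoot-rich gene models stood in it at a median of 0.757% of their shoot control level. These 72 were chosen to lie far below shoot in every root library, so their median was bounded by the choice. Shoot RNA at 50% would still lift every abundant shoot transcript in the control, these 72 included. A share of 0.757% covers 50% of the excess at 1.87% of the 855 gene models higher in the control. On a cold library under the desiccation label, the values point both ways. Among gene models at least 4-fold apart between desiccated and cold shoot, 52 were also 2-fold apart between desiccated and cold root. Of these 52, 48 (92.3%) went the same way in both tissues (middle 95% of random lists 25% to 78.6%), which argues against it. By list, 34 went the same way against 3 among the 240 higher, and 14 against 1 among the 246 lower under shoot desiccation. The median root difference was 0.22 for the first list and 0.07, within its random range of 0.01 to 0.10, for the second. Across all loci the root and shoot differences between desiccation and cold correlated little (r = 0.0231, rho = -0.0592). Of the loci 2-fold apart in both tissues, 277 went the same way and 172 opposite ways, against 111 each for independent lists. Among gene models 125 went the same way, against 34.0, and 29 opposite ways, against 34.4, which also argues against it. These 125 take in the 48 above, and the correlation was low here too (r = 0.0596, rho = -0.0405). Root desiccation correlated with shoot cold (r = 0.241, rho = 0.187) more than with shoot desiccation (r = 0.0492, rho = 0.00373). Root cold correlated less with shoot cold (r = 0.195, rho = 0.0717). The label question therefore stays open. An unusual root control cannot be told apart from a response common to both stresses, because there is 1 control. Salt-stressed root lay nearer to desiccation and cold than to the control at 53.9% of the 1869 gene models that moved together. Of these gene models, 81.9% changed in the same direction under salinity. Their median salinity change was 0.567 times the mean of the other changes. The biological explanation was not tested.

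The top of the stress rankings was held mostly by loci without an annotated gene. Pairs of a locus and a tissue in which it reached 100 FPKM were counted, so a locus can enter for both tissues. For loci without an annotated gene, 108 of 1478 pairs (7.31%) were listed at 0 in another library of that tissue. For gene models the number was 3 of 3366 pairs. Locus lengths and fragment numbers were not used here, and no explanation was tested.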
